A study of Mus musculus with 6 samples.

How the data were processed

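Liver RNA of C57BL/6 mice was sequenced in 6 libraries, 3 labelled dexmedetomidine and 3 labelled saline. Per the labels' protocols, total RNA was extracted with Trizol, checked for integrity, made into libraries with a VAHTS mRNA-seq kit and sequenced paired-end on an Illumina NovaSeq instrument. Reads were trimmed of adapters and low-quality sequence with fastp and mapped to a mouse genome with HISAT2, per the labels' protocols. The submitters' processing notes name HISAT2 2.1.0 and edgeR 1.20.0, without saying what edgeR was used for. The read counter, the annotation, the genome build and whether counting used strand are not given in the sources used here. The deposited table holds whole-number counts per Ensembl gene, not normalized, for 24449 genes in 6 columns named for the samples, and 0 of these genes had a total of 0. Every column was matched to its sample by name. Because strand and the treatment of reads with several matches are not given, values of overlapping or antisense genes and of near-identical family members (Cyp2a, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Mup, Saa and Acot genes among those named) are uncertain. There were 36 genes with a mean of at least 10 counts whose counts equalled those of another gene in all 6 libraries.

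Gene symbols, positions, exon lengths and GC content were taken from GENCODE release M21 on GRCm38, in which 24436 of the Ensembl identifiers (99.95%) were found. Positions are therefore those of this annotation, not of the build the submitters used. Each gene's exon length is the union of its exons, and its GC content is that of its longest transcript.

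Library totals ran from 15640535 to 19585046 counts. Genes were kept by edgeR's filterByExpr with the group (minimum count 10, minimum total 15), which left 13897 genes with 99.88% of all counts. Counts were expressed as CPM on library sizes scaled by TMM factors, and log2 CPM used a prior count of 2. The comparison of dexmedetomidine with saline was tested in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic, and 95% intervals use the test's degrees of freedom. A single value compared between 3 and 3 libraries by an exact permutation test cannot give a two-sided p under 0.1, so no such test was used. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. Intervals and p-values do not cover errors shared by all libraries.

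Before the data were examined, 53 gene lists were fixed, covering the cell cycle, growth factors, inflammation, metabolism, stress, hepatocyte zones, and the other cell types and neighbouring tissues a liver sample can hold. They name 1310 genes, of which 1256 were found in the table. Lists share some members. The 49 lists with at least 5 tested members were tested as sets with camera (limma 3.58.1) on voom values, two-sided, at a preset correlation of 0.01, adjusted over the 49 lists. The other 4 are given as values only. Each list was tested again with its own estimated correlation and with fry. A list's score in a library is the median over its members of log2 CPM minus the gene's mean over the 6 libraries. For each list the number of members past an adjusted p of 0.05 was counted over all genes tested and adjusted over the list alone.

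The rule for named genes was also fixed before the data were examined. It names up to 10 genes per direction with the largest fold change among those past the threshold, expressed at 1 CPM or more and with separate groups, and the 5 with the smallest adjusted p per direction. Where 0 genes pass, the 5 per direction with the smallest unadjusted p are given as values. In each list it names up to 4 members past the threshold over all genes or, where there are none, the 2 with the highest mean CPM, and it always names Mki67, Top2a, Pcna, Ccnd1, Ccnb1, Alb, Afp, Nlrp3, Il1b, Tnf, Il6, Hgf, Adra1b, Adra2a, Adra2b, Cyp7a1 and Saa1. Predicted genes and pseudogenes are not named. Genes named outside the rule are said to be. The values of some genes that the rule names are not reported here.

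The comparison was also made with RLE size factors, library size alone, upper-quartile factors, no filter, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom with and without library quality weights, the replicate number as a block, the table without mitochondrially encoded genes, the table without haemoglobin and the 20 most abundant genes, each library left out in turn, an adjusted p of 0.1, and a fold change of at least 2, all chosen before the data were examined. After the library structure had been seen, a correction for gene length and GC content was added (lowess smooths per library with a span of 0.3, used as offsets), and thinning of all libraries to the smallest total. All 10 ways to part the 6 libraries into 3 and 3 were fitted. The edgeR step was tested on simulated counts with the observed means, library sizes and gene-wise spread, with 200 of 13897 genes changed. It recovered 12% of 50 genes changed 2-fold, 88% of 50 changed 4-fold, 96% of 50 changed 8-fold and 100% of 50 changed 32-fold, with 15 calls among the unchanged genes. Genes were simulated as independent, without the library structure seen in the data. These shares are therefore not the power in the data, and 0 calls there do not exclude changes of such size. In simulated lists, the shifted list was called and 0 of 48 others were. Genes of these lists were simulated as independent, so the result does not show how often camera calls unchanged lists of correlated genes. A planted length trend gave 655 calls before the correction and 0 after it, and a planted GC trend of the same spread between genes gave 529 and 0.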

Results

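The data are mRNA-seq counts of liver from 8-week-old C57BL/6 mice, taken 48 hours after surgical removal of 70% of the liver, an operation after which the remaining liver regrows. Mice had received dexmedetomidine, a sedative that activates alpha-2 adrenergic receptors, at 25 µg/kg into the abdominal cavity 30 minutes before surgery, or are labelled as given saline. Groups follow the sample descriptions and treatment labels, because the treatment protocol given for the saline samples also describes the dexmedetomidine injection. There were 3 libraries per group and no unoperated or sham-operated samples, so the comparison asks how dexmedetomidine altered the transcriptome of the regenerating liver. The dexmedetomidine libraries held 19585046, 16932771 and 15640535 counts and the saline libraries 16495025, 18742446 and 18243672.

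The libraries did not part by group. On the first principal component of log2 CPM, with 45.4% of the variance, dexmedetomidine 1, dexmedetomidine 2 and saline 1 had negative scores and the other libraries positive ones. Dexmedetomidine 3 correlated at r = 0.983 with saline 3 and 0.979 with saline 2, but at 0.935 and 0.939 with the other libraries of its own group, across genes, which are not independent replicates. Saline 1 stood apart on the second component, with 29.5% of the variance, and reached at most r = 0.941 with any other library. In the pair of libraries closest to each other, counts differed by a mean chi-square of 18.0 per gene, more than counting error gives, so these were not the same library sequenced again. Dexmedetomidine 1, dexmedetomidine 2 and saline 1 also had relatively more counts in short genes, with Spearman rho across genes between expression relative to the gene mean and exon length of -0.325, -0.376 and -0.166, against 0.324 in dexmedetomidine 3, 0.364 in saline 2 and 0.340 in saline 3. The same 3 libraries had higher shares of counts in mitochondrial genes, 7.26, 9.61 and 8.56% against 5.68 to 6.06%, and in rRNA genes, 0.605, 0.224 and 0.230% against 0.0956 to 0.133%.

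**Figure D1:**
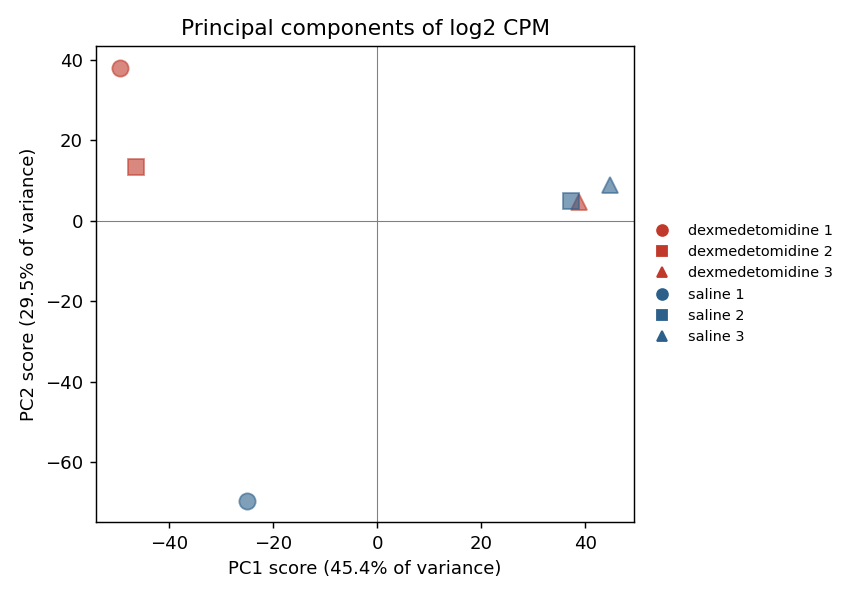
Scores of the 6 libraries on the first and second principal components of log2 CPM over 13897 genes, red for dexmedetomidine and blue for saline, with the marker giving the replicate. Dexmedetomidine 3 lies with saline 2 and saline 3, and saline 1 lies alone at the bottom.

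**Figure D2:**
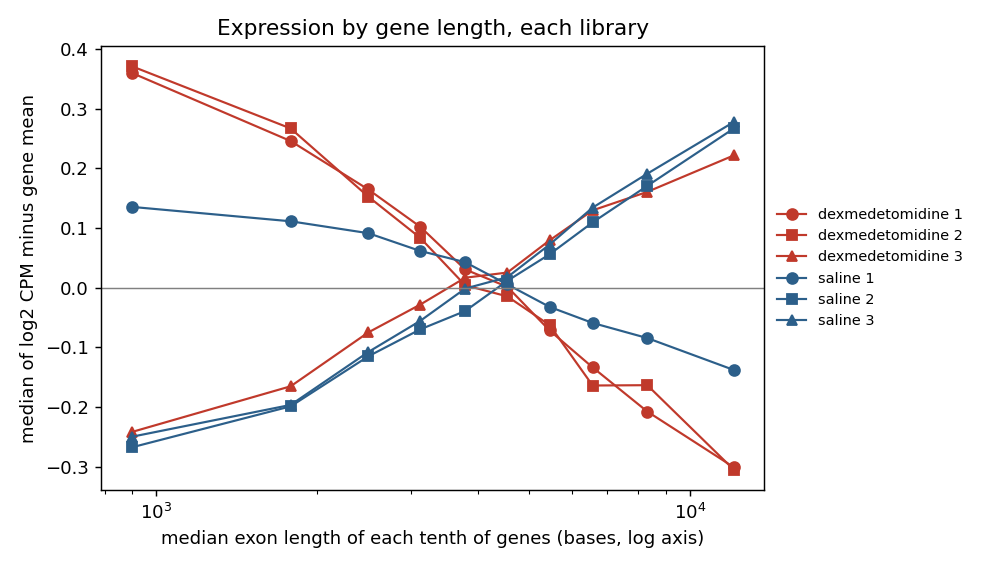
Median of log2 CPM minus the gene mean (vertical axis) in 10 groups of genes ordered by exon length (horizontal axis, bases, log scale), 1 line per library. In the shortest of these groups, with a median of 899 bases, dexmedetomidine 1 is at 0.36 and saline 2 at -0.27.

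No gene passed the adjusted threshold. The 5 genes with the smallest p in each direction were the cytochrome P450 genes Cyp2b9, Cyp2a4 and Cyp2a22 with Slc22a26 and Tagln3, higher in value with dexmedetomidine, and Ntrk2, Fdps, Msmo1, Mup7 and the P450 gene Cyp26a1, lower in value. Cyp2b9, a P450 gene usually more expressed in female than in male mouse liver (ENSMUSG00000040660, chromosome 7, 26173411 to 26210661), had 49.3 ± 23.0 CPM (SD, n = 3) with dexmedetomidine and 1.01 ± 0.849 CPM with saline (SD, n = 3), a log2 fold change of 5.58 ± 0.66 (SE). Cyp2a4 (ENSMUSG00000074254, chromosome 7, 26307169 to 26315088), another such gene, had 67.6 ± 49.4 against 1.33 ± 1.54 CPM. Its libraries ranged widely, from 10.7 CPM in dexmedetomidine 2 to 98.8 CPM in dexmedetomidine 1, and its neighbour Cyp2a5, named after its values were seen, is near-identical in sequence and had 182 CPM with dexmedetomidine and 105 CPM with saline. The edgeR quasi-likelihood test called 0 of 13897 genes at an adjusted p of 0.05, and the smallest adjusted p was 0.310, for Cyp2b9. At an unadjusted p under 0.05 there were 482 genes, 311 higher and 171 lower with dexmedetomidine. Leaving out 1 library moved this count to between 155 (without dexmedetomidine 1) and 3005 (without dexmedetomidine 3). The excess of higher genes was not kept either, with 1405 higher and 1600 lower without dexmedetomidine 3, 334 and 381 with the replicate number as a block, and 246 and 242 in limma-voom. DESeq2 called 13 genes, 6 higher and 7 lower, limma-voom called 0, limma-voom with library quality weights called 1781, and edgeR without a filter on low counts called 17. Every dexmedetomidine library lay above every saline library for 519 genes and below for 454, together 7.00% of genes, where chance gives 10%.

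For the other genes of the 5 per direction with the smallest unadjusted p, log2 fold changes with their standard errors were as follows, all with an edgeR adjusted p of 0.824 and with the groups' libraries apart. Cyp2a22 (ENSMUSG00000091867, chromosome 7, 26931631 to 26939384) was higher in value, at 2.30 ± 0.44. So were the organic anion transporter family gene Slc22a26 (ENSMUSG00000053303, chromosome 19, 7781041 to 7802667), at 2.52 ± 0.52, and Tagln3 (ENSMUSG00000022658, chromosome 16, 45711230 to 45724608), at 2.92 ± 0.64 from a level of only 1.05 against 0.136 CPM. Lower values were those of Ntrk2, a neurotrophin receptor (ENSMUSG00000055254, chromosome 13, 58806569 to 59133970), at -2.67 ± 0.41, and of Fdps and Msmo1, enzymes of cholesterol synthesis. Fdps (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959) was at -1.98 ± 0.41 and Msmo1 (ENSMUSG00000031604, chromosome 8, 64718139 to 64733792) at -1.39 ± 0.29, from 230 ± 47.3 CPM with saline to 87.7 ± 25.6 CPM with dexmedetomidine (SD, n = 3 each). Mup7, a major urinary protein gene usually higher in males (ENSMUSG00000073842, chromosome 4, 60066469 to 60070475), was at -2.29 ± 0.49, and Cyp26a1, which degrades retinoic acid (ENSMUSG00000024987, chromosome 19, 37697798 to 37701536), at -1.80 ± 0.39. All 10 genes except Tagln3 were among the 13 that DESeq2 called, and the remaining 4, named after their values were seen, were Cyp2c69, Cyp2c40, Insig1 and Lss. Mup and Cyp2 genes belong to families whose members can share reads.

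**Figure D3:**
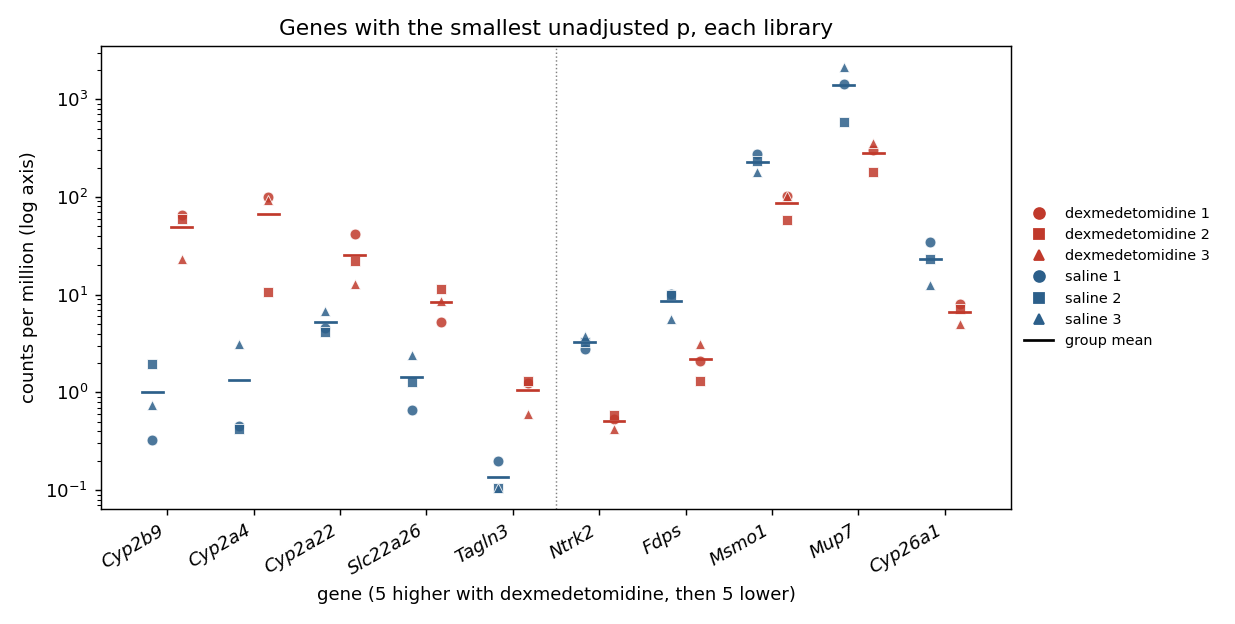
CPM (vertical axis, log scale) of the 5 genes with the smallest unadjusted p in each direction, 1 marker per library, red for dexmedetomidine and blue for saline, with bars at the group means. Cyp2b9 reaches 23.0 to 65.6 CPM with dexmedetomidine and at most 1.96 CPM with saline, and for each gene the markers of the groups do not overlap.

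Genes chosen in advance as readouts of regeneration, liver function, inflammation and the drug's receptors did not pass the test. Log2 fold changes, each with a 95% interval, were 0.68 (-0.99 to 2.34) for the proliferation marker Mki67, 0.57 (-0.853 to 1.996) for the topoisomerase gene Top2a, 0.76 (-0.12 to 1.64) for the replication clamp Pcna, 0.54 (-1.47 to 2.56) for the mitotic cyclin Ccnb1 and -0.46 (-1.83 to 0.91) for the G1 cyclin Ccnd1. Albumin (Alb) was at 0.05 (-0.98 to 1.09) and the fetal liver gene Afp at 0.54 (-0.58 to 1.67). The inflammasome sensor Nlrp3 was at 0.65 (-0.59 to 1.88), the cytokine gene Il1b at -0.24 (-1.25 to 0.76), the hepatocyte growth factor gene Hgf at -0.63 (-1.99 to 0.73), the acute phase gene Saa1 at -0.52 (-2.89 to 1.86) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.39 (-2.89 to 2.12). Of adrenergic receptors, Adra1b was at 0.55 (-0.05 to 1.15) and Adra2b at -0.26 (-1.16 to 0.63). Tnf, Il6 and Adra2a had too few counts to be tested, with at most 9, 1 and 3 counts in any library. The edgeR adjusted p of the tested genes in this group was 0.824 or more. The intervals are wide, and each includes a 2-fold difference in at least 1 direction.

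The gene lists fixed in advance were tested as sets, and 18 of 49 passed camera's test with a preset correlation of 0.01, 7 higher and 11 lower with dexmedetomidine. None of them had an adjusted p under 0.05 with an estimated correlation, where the smallest was 0.745, and fry called 1, the female-biased genes. Estimated correlations were 0.41 for cholesterol synthesis, 0.66 for DNA replication, 0.87 for G2/M and mitosis and -0.07 for female-biased genes. At the preset correlation at least 18 lists were called in 8 of the 10 ways to part the libraries into 3 and 3, the real one included. No member of any list passed over all genes tested. Per-library scores separated the groups for 3 lists, cholesterol synthesis, PPARα targets and female-biased genes. Values of list members below are log2 fold changes of genes that did not pass over all genes, and members of a list marked as past the threshold passed only adjusted over the list alone.

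Cholesterol synthesis genes were lower as a set with dexmedetomidine, and this was the list with the smallest p. The list holds enzymes of the pathway and targets of its regulator SREBP2. Of 26 members, 24 had a log2 fold change below 0 and the median was -0.92. Every dexmedetomidine library lay below every saline library for 18. Adjusted over the list alone, 18 members passed, against 0 over all genes. Besides Fdps and Msmo1, Hmgcs1, an early enzyme of the pathway named after its values were seen, was at -1.41 ± 0.34 (SE), from 511 to 192 CPM. The abundant member Sc5d was at -0.27 ± 0.39. Camera's adjusted p was 6.24e-21, and 0.745 with an estimated correlation, where the unadjusted p was 0.0304. The list passed at the preset correlation in each of the 6 fits that left out 1 library, with an adjusted p of at most 1.34e-11. Lipogenesis genes were also lower as a set, with 17 of 25 members below 0, a median of -0.32 and an adjusted p of 0.0186 (adjusted p = 0.752 with an estimated correlation). Scd1, which desaturates fatty acids, was at -0.96 ± 0.66 and Fads1 at 0.38 ± 0.31. In that list 0 members passed adjusted over the list alone, and without dexmedetomidine 2 the adjusted p was 0.0713.

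Targets of PPARα and genes of fatty acid oxidation were higher as a set, with 32 of 38 members above 0, a median of 0.33 and an adjusted p of 1.87e-06 (adjusted p = 0.752 with an estimated correlation). Scores per library were 0.30, 0.13 and 0.30 with dexmedetomidine and -0.58, 0.01 and -0.05 with saline. The fatty acid binding protein gene Fabp1 was at 0.95 ± 0.49 (SE), and 0 members passed adjusted over the list alone. The call held without each library in turn, with an adjusted p of at most 0.0101.

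Lists of sex-biased and of drug-metabolizing genes passed camera's test at the preset correlation, and these lists share members. Of 22 genes fixed in advance as usually more expressed in female liver, only 12 were among the genes kept for testing. The others bear on no result here. Of the 12 tested, 7 were above 0 and 5 below, with a mean of 1.16 and a median of 0.25. Camera's adjusted p was 0.00385 (adjusted p = 0.745 with an estimated correlation, unadjusted p = 0.0247). Fry's adjusted p for this list was 0.0270. Adjusted over the list alone 6 members passed, of which Cyp2b9, Cyp2a4, Cyp2c69, Cyp3a44 and Acot3 were higher and Ntrk2 lower (Cyp3a44 and Acot3 named after their values were seen). The 2 most abundant members, Rtn4 and Abcd2, were at 0.09 ± 0.29 and 0.40 ± 0.78 (SE). The list passed without each library in turn, with an adjusted p of at most 0.0365. Of sex-linked genes, also named after their values were seen, Xist, expressed in female cells, had at most 2 counts in any library, and the Y-linked Ddx3y had at least 697. The list that joins growth hormone signalling with male-biased genes was lower as a set. It had 23 of 28 below 0, a median of -0.24 and an adjusted p of 0.0236 (adjusted p = 0.752 with an estimated correlation). Its signalling members Socs2 and Cish, also named after their values were seen, lay above 0, at 0.72 ± 0.51 and 0.79 ± 0.48. Mup7 passed adjusted over the list alone, and the most abundant members, Serpina1e and Mup3, were at 0.13 ± 0.60 and -0.25 ± 0.33. That call was lost without dexmedetomidine 1 (adjusted p = 0.128), dexmedetomidine 3 (0.115), saline 2 (0.0508) or saline 3 (0.304).

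Cytochrome P450 and other drug metabolism genes were higher as a set, with 27 of 45 above 0, a median of 0.16 and an adjusted p of 0.000669 (adjusted p = 0.752 with an estimated correlation). The members past the threshold over the list alone were Cyp2b9, Cyp2a4, Cyp2c69 and Cyp2c40, while the most abundant, Cyp3a11 and Cyp2e1, were at -0.60 ± 0.82 and 0.45 ± 0.44 (SE). Cyp2b9, Cyp2a4 and Cyp2c69 are also members of the female-biased list, so this call is not separate from that one. The list's mean, 0.55, lay well above its median. The adjusted p was 0.109 without dexmedetomidine 3 and 0.0656 without saline 1. After correction for gene length and GC content, added after the data were seen, it was 0.0181 and the list's median was 0.00065.

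Cell cycle genes were higher as sets with dexmedetomidine, and saline 1 had the lowest score of the 6 libraries in both lists. In the G2/M and mitosis list, 39 of 40 members were above 0 with a median of 0.79, and camera's adjusted p was 1.83e-12 (adjusted p = 0.752 with an estimated correlation). Its score was -2.88 in saline 1, 0.31 and 0.57 in saline 2 and 3, and 1.19, 0.42 and 0.26 with dexmedetomidine. Mki67 had 21.8 CPM in saline 1 and 225 to 396 CPM in the other libraries. The anaphase activator gene Cdc20 was at 0.71 ± 0.90 (SE), and 0 members passed over all genes or adjusted over the list alone. Without saline 1 the list's adjusted p was 0.0900. In the DNA replication and S phase list, 40 of 41 members were above 0 with a median of 0.61 and an adjusted p of 3.18e-12 (adjusted p = 0.752 with an estimated correlation). Pcna was at 0.76 ± 0.38, and 0 members passed over all genes or adjusted over the list alone. Adjusted over the list alone, 22 members passed without dexmedetomidine 3. Its scores overlapped between groups, at 0.77, 0.43 and -0.26 with dexmedetomidine and -0.74, 0.14 and -0.28 with saline, and without saline 1 its adjusted p was 0.000401.

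**Figure D4:**
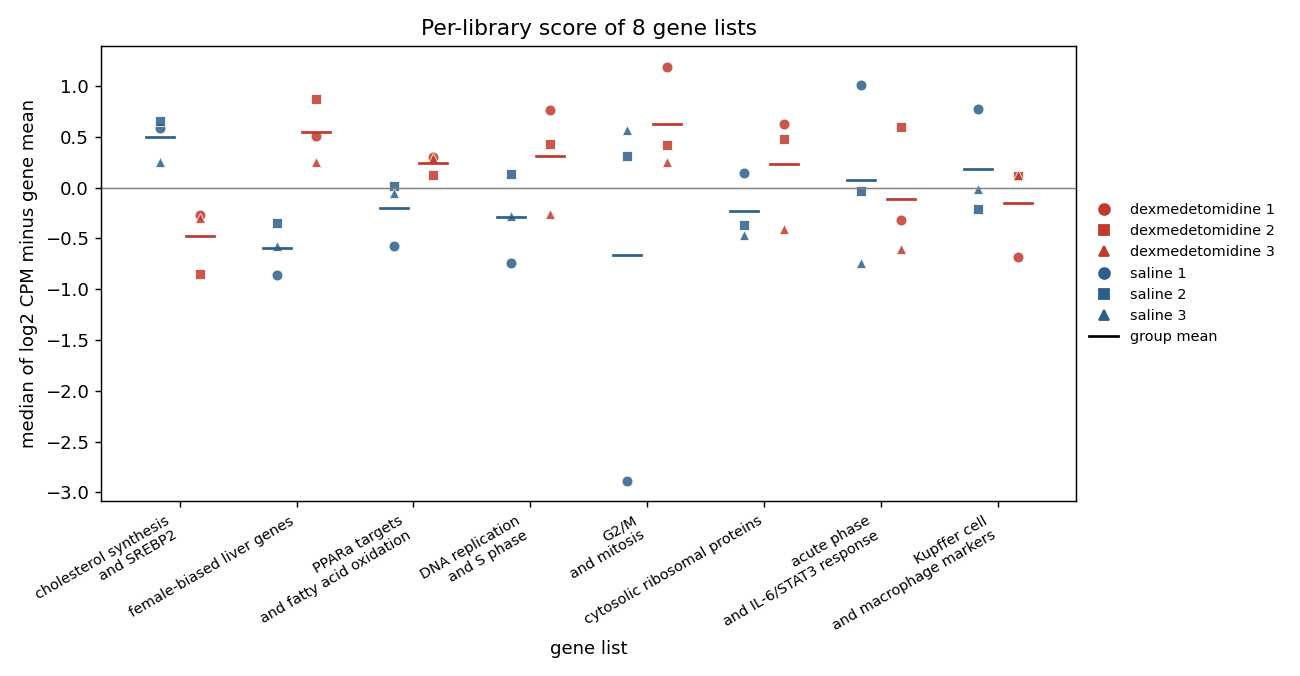
Scores of 8 gene lists per library, each the median over members of log2 CPM minus the gene mean (vertical axis), red for dexmedetomidine and blue for saline, with bars at group means. Groups are apart for cholesterol synthesis, female-biased genes and PPARα targets, and saline 1 lies at -2.88 for G2/M and mitosis.

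Cytosolic ribosomal protein genes and nuclear genes of oxidative phosphorylation were higher as sets. All 73 ribosomal protein genes were above 0, with a median of 0.50 and an adjusted p of 1.83e-12 (adjusted p = 0.752 with an estimated correlation), and Rpl4 and Rpsa were at 0.24 ± 0.24 and 0.65 ± 0.35 (SE). Of 44 oxidative phosphorylation genes 40 were above 0, with a median of 0.35 and an adjusted p of 3.37e-05 (adjusted p = 0.785 with an estimated correlation), and Sdha and Uqcrq were at -0.26 ± 0.28 and 0.80 ± 0.54. In both lists 0 members passed adjusted over the list alone. Members of both lists are short, with median exon lengths of 1840 and 1652.5 bases against 4182 bases over all genes tested. Their scores were positive in dexmedetomidine 1, dexmedetomidine 2 and saline 1 and negative in the other libraries, the same division as the trend with gene length. After correction for length and GC content the medians were 0.27 and 0.18, with adjusted p of 1.10e-07 and 0.0184.

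Genes of hepatocyte amino acid metabolism were lower as a set. In the urea cycle and amino acid catabolism list 29 of 36 members were below 0, with a median of -0.44 and an adjusted p of 0.000669 (adjusted p = 0.752 with an estimated correlation). Cps1, which makes carbamoyl phosphate for the urea cycle, was at -1.22 ± 0.38 (SE), from 3553 to 1526 CPM, and Mat1a at -0.70 ± 0.57. The call was lost without dexmedetomidine 3 (adjusted p = 0.255) or saline 1 (0.232). The periportal hepatocyte list, which shares Cps1 and other members with it, had 15 of 20 below 0, a median of -0.35 and an adjusted p of 0.0340 (adjusted p = 0.752 with an estimated correlation), with Arg1 at -0.37 ± 0.42. It was lost without dexmedetomidine 1 (adjusted p = 0.144), dexmedetomidine 3 (0.152), saline 1 (0.565) or saline 2 (0.0537). Liver growth factors, cytokines and their receptors were lower, with 21 of 27 below 0, a median of -0.34 and an adjusted p of 0.0272 (adjusted p = 0.752 with an estimated correlation), and the receptor genes Egfr and Il6st were at -0.27 ± 0.30 and -0.57 ± 0.33. This call was lost without dexmedetomidine 2 (adjusted p = 0.172), dexmedetomidine 3 (0.0557), saline 1 (0.265) or saline 2 (0.0588). In these 3 lists 0 members passed adjusted over the list alone.

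Markers of several non-hepatocyte cell types, and extracellular matrix genes, were lower as sets, again with 0 members past the threshold over all genes or adjusted over the list alone. Scores of each of these lists overlapped between groups. In dexmedetomidine 3 the sinusoidal endothelial score was 0.46, against 0.34, 0.20 and 0.11 with saline. Its other scores were 0.44 for matrix, 0.12 for Kupffer cells, 1.07 for mesothelial cells and -0.56 for cholangiocytes. Sinusoidal endothelial markers had 21 of 24 below 0, a median of -0.36 and an adjusted p of 0.000320 (adjusted p = 0.752 with an estimated correlation), with Plvap at 0.24 ± 0.19 and Ptprb at -0.75 ± 0.44 (SE), and without saline 1 the adjusted p was 0.0547. Extracellular matrix genes had 25 of 31 below 0, a median of -0.32 and an adjusted p of 0.000860 (adjusted p = 0.785 with an estimated correlation), with fibronectin (Fn1) at -0.50 ± 0.30 and Sparc at -0.09 ± 0.28. That call was lost without dexmedetomidine 2 (adjusted p = 0.0631) or saline 1 (0.185). Markers of Kupffer cells, the resident macrophages, had 16 of 17 below 0, a median of -0.44 and an adjusted p of 0.00389 (adjusted p = 0.785 with an estimated correlation), with Cd5l and Slc40a1 at -0.44 ± 0.33 and -0.39 ± 0.28. It was lost without dexmedetomidine 1 (adjusted p = 0.155) or saline 1 (0.738). Cholangiocyte markers had 13 of 17 below 0, a median of -0.82 and an adjusted p of 0.00464 (adjusted p = 0.752 with an estimated correlation), with osteopontin (Spp1) at -1.65 ± 0.58 and Anxa4 at 0.18 ± 0.21. Their score was 1.25 in saline 1 and at most 0.16 in any other library, and the call was lost without dexmedetomidine 3 (adjusted p = 0.186) or saline 1 (0.430). Mesothelial markers had 5 of 6 below 0, a median of -0.70 and an adjusted p of 0.0337 (adjusted p = 0.752 with an estimated correlation), with Slc39a8 at 0.03 ± 0.25 and Efemp1 at -0.17 ± 0.50. Their call was lost without dexmedetomidine 2 (adjusted p = 0.198) or saline 2 (0.108), and after correction for length and GC content (0.0585).

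The remaining 31 lists were not called, with camera adjusted p from 0.0521 to 0.951. Inflammatory and immune lists among them were those of the acute phase, with 27 of 30 members below 0, a median of -0.36 and an adjusted p of 0.103, and inflammasome and NF-κB genes (17 of 22 below 0, adjusted p 0.113). Others were the interferon response (21 of 35 above 0, 0.261), antigen presentation (10 of 16 above 0, 0.173), monocytes and dendritic cells (15 of 17 below 0, 0.0521), neutrophils (8 of 10 below 0, 0.352), B and plasma cells (8 of 9 above 0, 0.333) and T, NK and innate lymphoid cells (4 of 6 above 0, 0.910). Their most abundant members were at -0.56 for complement C3 and -0.11 for Hp, and 0.46 for Cxcl1 and -0.02 for Rela. Those of the interferon and antigen lists were at 0.08 for Iigp1 and 0.43 for Stat2, 0.29 for B2m and -0.02 for H2-K1. Of immune cell markers, the values were -0.96 for Lcn2 and -0.02 for Hdc, 0.24 for Ighm and 0.66 for Igkc, and 0.0045 for Il2rb and -0.88 for Thy1. Fn1 and Spp1 are also the most abundant monocyte and dendritic cell members. The acute phase score was 1.01 in saline 1 and 0.60 in dexmedetomidine 2, and -0.75 to -0.03 in the other libraries.

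Metabolic and hepatocyte lists without a call were gluconeogenesis and glycogen (16 of 19 below 0, adjusted p 0.0521), glycolysis (12 of 23 above 0, 0.951), bile acid synthesis and transport (20 of 25 below 0, 0.246), secreted proteins and lineage factors (19 of 29 above 0, 0.265) and fetal liver and progenitor genes (12 of 17 below 0, 0.101). The same held for pericentral hepatocyte genes (12 of 21 above 0, 0.223), the circadian clock (12 of 23 above 0, 0.789), glucocorticoid receptor targets (12 of 18 below 0, 0.265) and adrenergic receptors (3 of 5 below 0, 0.545). Log2 fold changes of their most abundant members were -0.32 for Pck1 and -0.84 for Tat, 0.36 for Ldha and 0.03 for Tpi1, -0.18 for Cyp2c70 and -0.12 for Slco1b2. They were 0.23 for Ahsg, 0.63 for Cyp2c29, 0.19 for Tef and -0.65 for Rora, and 1.49 for Adrb3. Of the others named by the same rule, Aldoa (ENSMUSG00000030695) was at -0.10, and Alb, Spp1, Cyp2e1, Lcn2 and Adra1b are given above.

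Growth, stress and structural lists without a call were G1 cyclins, CDK inhibitors and immediate early genes (14 of 26 above 0, adjusted p 0.449), Hippo/YAP targets (11 of 13 below 0, 0.0521), p53 targets and apoptosis (15 of 30 above 0, 0.159), and ribosome biogenesis (21 of 34 below 0, 0.451). Of stress lists these were heat shock and chaperones (12 of 18 above 0, 0.0521), ER stress (18 of 31 above 0, 0.476), autophagy and lysosome (18 of 25 below 0, 0.265), and NRF2 and oxidative stress (16 of 28 above 0, 0.951). The others were metal-binding and iron genes (8 of 15 below 0, 0.268), the cytoskeleton (15 of 26 above 0, 0.352), mitochondrially encoded genes (10 of 11 above 0, 0.101), stellate cells and fibroblasts (15 of 25 below 0, 0.870), erythroid genes (6 of 10 above 0, 0.576) and adipocyte genes (5 of 7 above 0, 0.101). Their most abundant members were at 0.05 for Egr1, -0.23 for Amotl2 and -0.33 for Axl, 0.23 for Ei24 and -0.05 for Mcl1, -0.09 for Ncl and 0.20 for Npm1. In the stress lists they were at 0.12 for Hsp90ab1 and 0.32 for Hspa8, -0.13 for Calr and -0.14 for Hspa5, -0.42 for Ctsl and -0.02 for Ctsb, 0.16 for Mgst1 and 0.13 for Gpx1, and in the others at 0.38 for Fth1 and 0.37 for Mt1, 0.21 for Actb and -0.58 for Krt8, 0.10 for mt-Co1 and 0.22 for mt-Cytb, 0.15 for Dcn and -0.74 for Col3a1, -0.08 for Hbb-bs and 0.03 for Hba-a1, and -0.25 for Car3 and 0.60 for Lpl. Camera's direction differed in sign from the median or the mean for 6 of the uncalled lists, those of neutrophils, adrenergic receptors, the circadian clock, T and NK cells, NRF2 and glycolysis. The 4 lists too small to test were platelet markers (Clec1b -0.50, Itgb3 -0.15), pancreatic acinar genes (Cela1 0.0017, Ctrl 0.67), gastrointestinal epithelium genes (Anpep 0.0099, Fabp2 1.04) and skeletal muscle genes (Neb -0.18, Des -0.21), with medians of -0.33, 0.33, 0.0099 and 0.13.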

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

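The correction for gene length and GC content and the thinning of libraries were chosen after the data were seen, and the other alternatives before. The count of genes called was 0 in 18 of 21 alternatives, leave-one-out included. Among these the fold threshold could only give 0, as no gene passed without it, and the leave-one-out fits hold fewer libraries. The count was 17 without a filter, 13 with DESeq2 and 1781 with library quality weights. These weights were lowest for dexmedetomidine 3 and saline 1, at 0.314 and 0.360, and highest for saline 2, at 2.57. All 13 DESeq2 genes were among the 1781, and 10 were also called without a filter. The cause was not tested. With the replicate number as a block, edgeR called 0 genes, with 715 at an unadjusted p under 0.05. Deviations of same-numbered libraries from their group means correlated at 0.13, -0.23 and 0.35 across genes, and saline 1 correlated better with dexmedetomidine 2 (0.37) than with its own number, so the numbers were not taken as pairs.

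Of the 18 lists called, 18 were called in the same direction with RLE factors, library size alone and upper-quartile factors. The same held without mitochondrial genes, without the most abundant genes and after thinning. With the block, with DESeq2 and after length and GC correction 17 were called, the mesothelial list being the call lost in each. Without a filter 16 were called, and 11 with quality weights, and none reversed in any alternative. The limma-voom alternative changed only the gene test and kept the list test of the main fit, so it bears on no list. Lists called numbered 0 higher and 0 lower with an estimated correlation, 1 higher and 0 lower with fry, and 6 lower with quality weights. Leaving out 1 library gave 7 to 11 lists higher and 5 to 18 lower. The 5 was without saline 1, which lost 9 of the 18 calls, and the 18 without saline 3, and 6 lists passed in all 6 such fits. For the DNA replication and the G2/M lists the adjusted p was 0.752 with an estimated correlation and 0.810 with fry, and without 1 library ranged from 7.36e-24 to 0.000401 and from 7.18e-28 to 0.0900 (without saline 1).

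Members past the threshold adjusted over the list alone were 12 in each of these lists without a filter, 10 in the DNA replication list with quality weights, and 0 to 22 in that list without 1 library (22 without dexmedetomidine 3). Over all genes, quality weights called 7 members of the DNA replication and 1 of the G2/M list. Of 2225 values of 118 named genes under alternatives, 2165 were within 1 SD between libraries of the reported value, 40 were called, and the sign changed for 50 genes in at least 1 setting. The 5 genes per direction with the smallest p kept their sign, Cyp2b9 between 5.18 and 6.49 and Msmo1 between -1.54 and -1.17. Depth limits the lowest genes, such as Tnf, Il6 and Adra2a, which could not be tested.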

Other observations

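The list tests and the fits without 1 library were planned before the data were seen, while their use as tests of explanations, the splits, the Xist counts, the length and GC correction and the thinning were chosen after the results were seen. Genes named here for saline 1 and for growth hormone signalling, and Fgf21, Cyp4a10 and Cyp4a14, were chosen after their values were seen. Several genes had values in saline 1 outside the range of the other libraries. Ccnb1 was at 2.29 CPM there and at 60.7 to 91.1 CPM in the other libraries, Cyp7a1 at 0.654 against 27.2 to 92.4 CPM, and the acute phase genes Saa1, Saa2 and Lcn2 at 12797, 16926 and 7697 CPM against at most 7332, 9695 and 2752 CPM, each of these last in dexmedetomidine 2. Saa1 and Saa2 are near-identical and can share reads.

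Growth hormone sets the sex bias of many liver P450 genes, and other genes of its signalling did not pass the test here. Socs2 and Cish, induced by growth hormone through STAT5, were at 0.72 ± 0.51 and 0.79 ± 0.48 (log2 fold change, SE), Igf1 at -0.20 ± 0.26, and Bcl6, a repressor of female-biased genes, at -0.68 ± 0.56. The hepatokine gene Fgf21 had 7.32, 0.712 and 9.84 CPM with dexmedetomidine and 0.523, 0.636 and 1.27 CPM with saline, so that its groups overlapped. The PPARα target Cyp4a10 had a mean of 280 against 98.1 CPM, with the groups' libraries apart. Cyp4a14, a more abundant member of the same list, overlapped between groups. It had 895, 555 and 391 CPM with dexmedetomidine and 90.6, 629 and 147 CPM with saline. None of these passed over all genes in edgeR with the filter on low counts. Without that filter Fgf21 was called by edgeR (adjusted p = 0.0351, against 0.125 with DESeq2 and 0.824 in the filtered fit).

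The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes with edgeR, a count that all 10 of the 10 splits meet by necessity, so that it bears on nothing, and the highest other count was 3287. That count came from dexmedetomidine 1, dexmedetomidine 2 and saline 1 against the rest, while 8 of the 9 other splits gave 0, which points to a structure of the samples. It is the division already seen on the first principal component, and it would be the treatment split if the labels of dexmedetomidine 3 and saline 1 had been exchanged. With DESeq2 the real split gave 13 genes, 3 of 10 splits gave as many, and the highest other gave 3943. For lists called by camera the real count was 18, met by 8 of 10 splits, and the highest other was 23. A camera p as small as the real one came from 2 of 10 splits for the DNA replication list (2.59e-13, smallest other 1.65e-29) and from 6 of 10 for the G2/M list (9.78e-14, smallest other 2.24e-20). For cholesterol synthesis only the real split, 1 of 10, had a p as small (1.27e-22, smallest other 1.28e-11), and the same held for the female-biased list, 1 of 10 (0.000864, smallest other 0.174). Both lists were taken up because they followed the labels, so a first rank of the real split was likely from the start and lends them no support. For PPARα targets the real split gave 1.91e-07, and dexmedetomidine 1, dexmedetomidine 3 and saline 2 against the rest gave a smaller p, 3.70e-08.

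The division of the libraries across the groups was weighed against 3 technical explanations. No biological explanation was tested for it, nor RNA quality, although mitochondrial and rRNA gene shares follow the same division. A trend with gene length and GC content, in the form that the correction models, is argued against as the whole cause. That split still gave 1244 genes after a correction that removed every call from counts simulated with a length trend or with a GC trend. The simulated trends were planted in the same lengths and GC values that the correction uses, so a trend of another form is not excluded. The fall from 3287 leaves such a trend open as a part. Library size is argued against by 3216 genes after thinning to equal totals. Exchanged labels of dexmedetomidine 3 and saline 1 remain open and cannot be told apart from a difference between livers: dexmedetomidine 3 correlated better with saline 2 and 3 than with its own group by a mean of 0.0442 in r, but saline 1 was hardly closer to dexmedetomidine 1 and 2 than to its own group, by 0.00234, and with the labels exchanged the camera p of the cholesterol and female-biased lists, picked because they follow the labels, rises to 0.0356 and 0.364.

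The higher cell cycle lists may come from saline 1 in the case of mitosis, since that call was lost without this library (adjusted p = 0.0900) and kept without each other library in turn. For DNA replication the call was kept without saline 1 at the preset correlation (adjusted p = 0.000401), so it did not rest on this library alone. The scores of the other libraries overlap between groups. At that setting another split of the libraries gave a smaller camera p (1.65e-29) than the real one (2.59e-13). The kept call therefore does not decide whether saline 1 is the source of the difference between the groups. With an estimated correlation the adjusted p was 0.875 without saline 1 and already 0.752 with all 6 libraries, so that fit decides nothing about saline 1. A trend with gene length and GC content, in the form that the correction models, is argued against for both lists by their medians. After correction these were 0.64 for DNA replication and 0.79 for G2/M and mitosis, against 0.61 and 0.79 before it. The lists' median exon lengths, 4268 and 4520 bases, lay near 4182 bases over all genes tested, so length correction could move them little. The larger camera adjusted p after correction, 4.98e-13 at the preset correlation, therefore adds little. An effect of dexmedetomidine on the cell cycle remains an untested possibility beside these.

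Higher female-biased genes and lower cholesterol synthesis genes were weighed because their scores parted the groups, and the other lists but PPARα targets and the cell cycle lists were not compared over the splits. Animals of mixed sex are argued against by Xist, with at most 2 counts in any library. Gene length and GC content are argued against by an adjusted p after correction of at most 0.00159 for both lists. The cholesterol list's median exon length was 4409 bases, against 4182 bases over all genes tested, so length correction could move that list little. Lower food intake after the drug is a candidate explanation, since fasting lowers SREBP2 and lipogenesis genes and raises PPARα targets. It would also raise gluconeogenesis genes, which lay lower (16 of 19 members, camera adjusted p = 0.0521). Their score was highest in saline 1, at 0.45, against 0.03 and -0.22 in saline 2 and 3. With dexmedetomidine it was -0.21, -0.06 and -0.09, so the groups overlapped. The adjusted p of the gluconeogenesis and glycogen list was 0.0181 with length and GC offsets, and ranged from 0.000654 without saline replicate 3 to 0.810 with fry. As that list did not pass in the fit reported, the explanation cannot be told apart from a direct effect of dexmedetomidine on the liver, for which these data hold no test.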
